A study of Mus musculus with 4 samples.

How the data were processed

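RNA of cultured mouse mesenchymal stem/progenitor cells (MSPC), the fibroblast-like stromal cells that can be grown from bone marrow, was sequenced in 4 libraries. Per the labels, 2 libraries came from wild-type (WT) cells and 2 from Asxl1-/- cells on a C57BL/6 background. The cells were at passages 5 to 10, grown in MesenCult medium with 20% supplement and replated at 80 to 90% confluency, and total RNA was taken up in Trizol. Groups were read from the genotype label, and replicates were numbered in accession order, so a replicate number pairs no samples. The labels do not say whether the libraries of a group came from separate animals, so p-values measure only the spread between these samples. Whole chromosomes argue against a spread that is technical alone. Genes of chromosome 9 had a median log2 difference from the mean of the other libraries of -0.497 and 0.423 in WT replicates 1 and 2. Those of chromosome 3 had -0.595 and -0.016 in Asxl1-/- replicates 1 and 2. Whether the cultures came from separate animals stays open.

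Per the submitters' processing notes, reads were handled with TopHat2 (version 2.0.3), Cufflinks (version 2.2.1) and Cuffdiff on the mouse build mm10. The gene annotation, the library kit and its strandedness are not given in the sources used here. Overlapping and antisense genes, and genes with near-identical copies, are therefore uncertain. The deposited FPKM table (fragments scaled to transcript length and to the number of mapped fragments, as Cufflinks gives them) holds 24487 rows, each with a symbol and a position. A deposited log table, whose name says log10, was used only for a check. All 60823 values above 0 that could be matched equalled log2 of the FPKM within 0.001, and 0 stood where the FPKM was 0. The authors' deposited Cuffdiff table gives an FPKM per group, a log2 fold change of Asxl1-/- over WT, a p-value and a q-value for 23997 rows. The FPKM and log tables each hold 2 further columns of per-sample values that match no sample of the series, 4 in all, and these were not used. In the Cuffdiff table the group values were a median of 1.16 times (WT) and 1.25 times (Asxl1-/-) the mean of the 2 libraries, so its scaling between the groups differs from that of the FPKM table.

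File starts plus 1 equalled a GENCODE transcript start of the same symbol for 12048 of 22946 genes, against 1035 without the 1, so starts are given here with 1 added. The number of reads per library is unknown. At FPKM between 0.003 and 0.1, ratios of a gene's values between libraries pile up at small whole-number ratios of reads. From these steps the depths of WT replicate 2, Asxl1-/- replicate 1 and Asxl1-/- replicate 2 were 0.984, 1.03 and 0.956 times that of WT replicate 1. Rows with a genomic span under 300 bp, mostly small RNAs whose FPKM are inflated by their length, held 24.9%, 40.9%, 22.6% and 21.4% of the FPKM sum of WT replicates 1 and 2 and Asxl1-/- replicates 1 and 2.

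FPKM are not read counts, so genes were tested with limma (version 3.58.1, R version 4.3.3; lmFit and eBayes with a variance trend) on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 4 libraries entered, 11485 in all. Fold changes are on that scale, Asxl1-/- minus WT, and understate the change of low genes. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Gene lists fixed beforehand were tested with limma's camera at a preset correlation between genes of 0.01, a two-sided comparison of the list with the other genes, for the 22 lists with at least 5 tested members, and adjusted over these lists. Of 701 symbols in the 29 lists, 697 matched a row. Tables and figures were made in Python (version 3.11.15; pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9).

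The rule for named genes takes Asxl1, then per direction the 10 genes with the largest fold change among those past the adjusted threshold with no overlap between the groups. Where fewer than 5 pass, genes with an unadjusted p under 0.05 and no overlap fill the 10, as values only. Unnamed gene models, small RNAs named Snor or Mir, Y-linked genes and Xist are counted but not named by this part. From each list, up to 4 tested members with the smallest p are named. The design, the lists, this rule and most alternatives (pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median ratio scaling, quantile normalization, eBayes without trend or robust, each library left out, an estimated correlation, camera on ranks and fry) were set before the data were examined. Chosen after seeing the data were the fit without genes under 300 bp, the fit with the mean level of macrophage markers as covariate, the fit with each library's chromosome medians removed, and the comparison of 1 library with 1 library low in macrophage markers. The option by which camera follows the variance trend was also set afterwards. A run without it had given 2 lists higher and 2 lower. It was then switched on to match the gene test, which gives 1 and 1, and both counts are reported. The lists no longer called with it were the osteoblast list (lower) and the Hox list (higher). Whether a list turned direction is judged by its median, which was chosen after the test's direction had been tried; by the median 40 values turned, and by the direction of the test 44.

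The tests were run on simulated data with 200 changed genes of 11485 in each of 5 runs per size, for Asxl1-/- against WT, 2 against 2. At a log2 change of 1 or 2, 0% of the changed genes passed the adjusted threshold, and 60.4% and 92.4% had an unadjusted p under 0.05. At a log2 change of 4, 76.9% passed. False calls over the 5 runs numbered 1, 0 and 42 for the 3 sizes. Lists of 30 genes, lowered by a log2 change of 1 in every run, had an unadjusted camera p under 0.05 in 5 of 5 runs beside each size. Unshifted lists did in 0. Genes were drawn independently of each other, so these runs cannot tell how often lists of genes that move together are called falsely.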

Results

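Gene expression was measured by RNA sequencing in cultured bone marrow mesenchymal stem/progenitor cells (MSPC) of mice with and without Asxl1, a chromatin regulator that binds the BAP1 histone deubiquitinase and acts in the Polycomb system. The title of the series puts the question: what the loss of Asxl1 does to the self-renewal and cell fate of these stromal cells. There were 2 wild-type (WT) and 2 Asxl1-/- libraries. FPKM summed to 563749 and 703730 in the WT libraries and to 553089 and 497340 in the Asxl1-/- libraries, and 10951 to 11363 rows per library reached 1 FPKM. The read number per library is unknown, and relative depths lay between 0.956 and 1.03. Across genes, which are not independent replicates, Pearson's r between libraries was 0.867 within WT, 0.874 within Asxl1-/- and 0.84 to 0.878 between the groups, so the groups did not separate by overall similarity.

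Asxl1 itself (mm10 chromosome 2, 153346139 to 153404007) stood at 14.6 and 11.2 FPKM in the WT libraries and at 0.273 and 0.312 FPKM in the Asxl1-/- libraries. The means were 12.9 ± 2.37 and 0.293 ± 0.0279 FPKM (SD, n = 2 each). The log2 fold change was -3.41 with a standard error of 0.29, and its limma adjusted p of 0.215 lay above the threshold. In the authors' deposited table the gene is marked significant, with a log2 fold change of -5.34 and a q of 0.00836. The limma value depends on the pseudocount, with -5.04 at 0.1 and -4.07 at 0.5. The levels follow the genotype labels in all 4 libraries.

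The genes named next had the largest fold changes among those with an unadjusted limma p under 0.05 and no overlap between the groups. The largest higher levels in Asxl1-/- by this rule were those of Cygb, a globin of fibroblast-like cells, at 68.8 and 27.6 FPKM against 0.594 and 0.548 in WT (log2 fold change 4.83, standard error 0.48), and of Avpr1a, a vasopressin receptor, at 60.4 and 8.01 against 0.0155 and 0.0472. Angpt2, a ligand of the Tek receptor, stood at 109 and 8.93 FPKM against 0.85 and 0.541. Igfbp4, a secreted binding protein of insulin-like growth factors, stood at 136 and 1088 against 40.9 and 16.2, and the basement membrane collagen Col4a1 at 269 and 941 against 73.8 and 35.0. Rgs16, a regulator of G protein signalling, had close replicates, with 76.5 and 77.6 FPKM against 4.97 and 9.81. The microfibril gene Mfap5 stood at 88.3 and 133 FPKM against 22.6 and 3.42, and the laminin-related Ntn4 at 6.51 and 53.2 against 0.139 and 2.71. The transcription factor gene Ebf2, at 4.77 and 24.1 against 0.335 and a value listed at 0, and Rbpms, at 16.0 and 27.4 against 2.44 and 0.491, complete the 10. With 1 library left out the log2 fold change ran from 2.56 to 6.03 for Angpt2, 2.35 to 5.34 for Igfbp4, 2.21 to 4.63 for Mfap5 and 1.87 to 4.72 for Ntn4. Their standard errors ran from 0.35 for Rgs16 to 1.17 for Angpt2.

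By the same rule, the largest lower levels were those of Sfrp2, a secreted Wnt modulator, which stood at 136 and 420 FPKM in WT, at 6.97 in Asxl1-/- replicate 1 and was listed at 0 in Asxl1-/- replicate 2. Ptgis, the prostacyclin synthase, stood at 24.4 and 52.5 FPKM in WT against 0.0966 and 0.052 (log2 fold change -5.10, standard error 0.43). The surface peptidase Mme (CD10) stood at 123 and 26.4 against 2.42 and 0.489, and the surface protein Cd34 at 136 and 115 against 0.84 and 12.5. Clec11a, a secreted growth factor that promotes bone formation, stood at 13.5 and 78.1 against 0.149 and 1.38. The heparin-binding growth factor Ptn stood at 81.4 and 122 against 0.39 and 17.0. Capn6 stood at 84.3 and 27.6 against 0.0772 and 2.51, and the aldehyde dehydrogenase Aldh3a1 at 44.7 and 13.8 against 0.754 and 0.232. Itm2a, at 3.81 and 105 against 0.55 and a value listed at 0, and the phosphatase gene Ptprv, at 9.47 and 76.2 against 1.18 and 0.965, complete the 10. With 1 library left out the log2 fold change ran from -6.18 to -2.49 for Ptn, -6.42 to -1.95 for Itm2a and -5.22 to -2.34 for Ptprv.

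**Figure D1:**
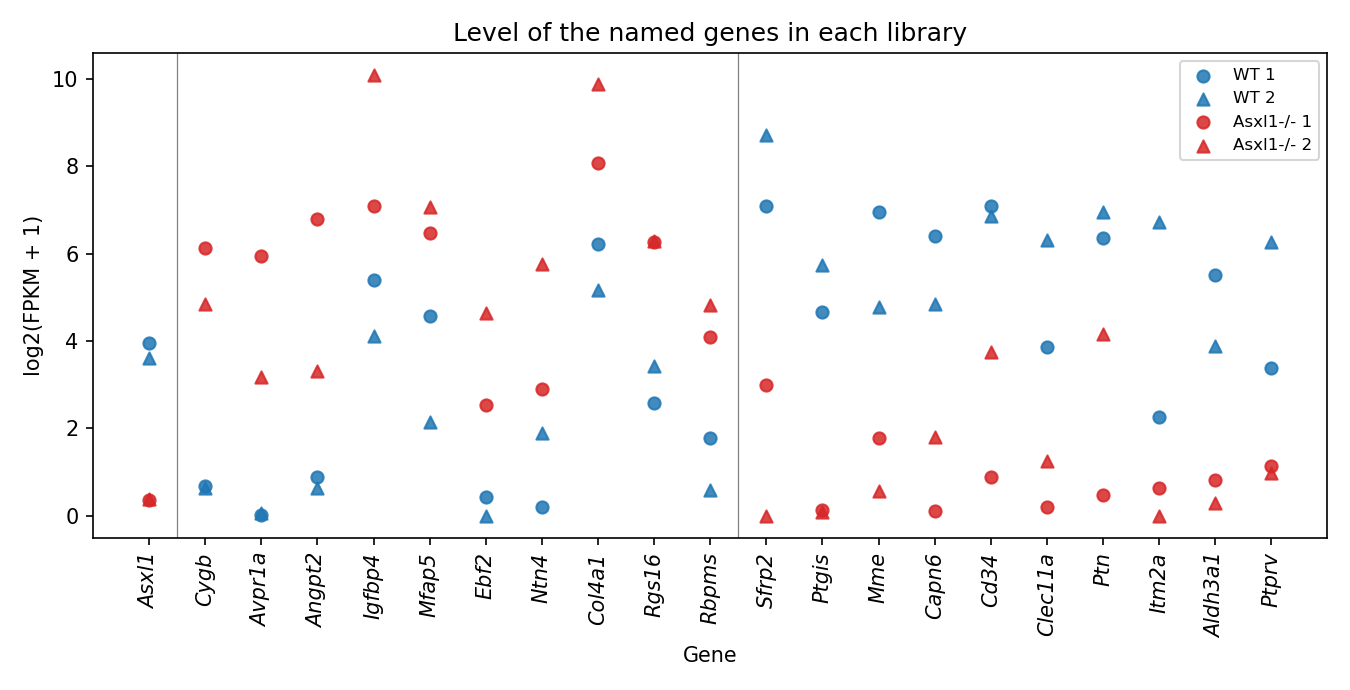
Level of Asxl1 and of the 10 higher and 10 lower genes named above (x axis) as log2(FPKM + 1) (y axis), 1 point per library, with circles for replicate 1 and triangles for replicate 2. The 10 per direction are the largest fold changes among genes with an unadjusted limma p under 0.05 and no overlap between the groups. Both Asxl1-/- points lie on the same side of both WT points for each gene, by the rule that chose them; the gap is narrow for Ntn4 and wide for Cygb.

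None of these 20 genes passed the adjusted threshold, with limma adjusted p between 0.215 for Ptgis and 0.617 for Itm2a, so they are given as values. Of 11485 genes tested with limma, 0 rose and 3 fell at an adjusted p under 0.05. The 3, named after their values were seen, were the small nucleolar RNA genes Snora15, Snora69 and Snora47, each under 300 bp long and listed at 0 in both Asxl1-/- libraries; without genes that short, 0 fell. An unadjusted p under 0.05 was reached by 909 genes, 288 higher and 621 lower, where 574 are expected by chance. The share of higher genes among them was 31.7%, against 46.6% after median ratio scaling and 42.9% after quantile normalization, which move the median fold change of all genes from -0.07 to 0.02. Both Asxl1-/- libraries lay above both WT libraries for 15.6% of genes and below them for 25.2%, against 16.7% per direction by chance.

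The authors' deposited table tells of more calls. It marks 121 of 12881 tested genes as significant, 70 higher and 51 lower in Asxl1-/-, and includes 4 of the 10 higher and 7 of the 10 lower genes named above. Members of the fixed lists among its calls, picked after its values were seen, numbered 14. In the authors' deposited table the collagen genes Col4a1 (group values 62.4 and 760 FPKM), Col4a2 (46.4 and 518) and Col8a1 (23.5 and 125) were higher in Asxl1-/-. So were the Wnt modulator Sfrp1, the Wnt receptor Fzd7, the BMP antagonist Grem1, the peptide hormone gene Adm and the smooth muscle actin Actg2. In the authors' deposited table Sfrp2, Ptn, the cartilage collagen Col11a1, the chemokines Cxcl1 and Cxcl5 and the bone sialoprotein Ibsp were lower. In the FPKM table the groups overlapped for 3 of these. Cxcl5 stood at 90.2 and 0.836 FPKM in WT against 2.29 and 6.80 in Asxl1-/-, so WT replicate 2 lay below both. Ibsp was above 0 only in WT replicate 2, at 1.76, and Grem1 stood at 22.9 and 40.2 in WT against 37.6 and 244. Of the 121 calls, 120 had a row in the FPKM table. For 98 the libraries of the groups did not overlap, for 22 they did, and for 31 over 90% of the higher group's FPKM came from 1 library. Examples of the latter in the FPKM table, chosen after their values were seen, are the retinoic acid enzyme gene Aldh1a2, at 248 FPKM in Asxl1-/- replicate 1 and 2.70 in replicate 2, and the growth factor gene Igf2, at 0.318 and 96.1. Of 103 calls tested with limma, all had the same sign there, 69 had an unadjusted p under 0.05 and 0 passed the adjusted threshold. The authors' group values follow the means of these same libraries, so the shared sign is no independent support.

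The proliferation list had the smallest camera p of the 22 lists. It fell in Asxl1-/-, with a median log2 fold change of -1.11 over 38 genes and 37 of them negative (camera adjusted p = 1.02e-18). The adjusted camera p was 0.975 with an estimated correlation, 0.378 for this list, which rests on 2 residual degrees of freedom. With fry, which asks whether the list moves at all and compares it with no other genes, p was 0.0461 and the adjusted p 0.992. Both Asxl1-/- libraries lay below both WT libraries for 36 of the 38, against 25.2% of all genes tested and 16.7% by chance. Genes of the list are correlated, so these are not independent events. Adjusted over the list alone 24 genes fell, and over all genes tested 0. Birc5, an inhibitor of apoptosis needed for chromosome segregation, stood at 35.0 and 34.6 FPKM in WT against 16.0 and 15.3, and the cyclin Ccnb2 at 25.4 and 28.5 against 11.9 and 13.0. The kinesin Cenpe stood at 13.9 and 9.53 against 2.74 and 3.64, and the replication helicase subunit Mcm5 at 31.1 and 18.1 against 8.42 and 6.46. WT replicate 1, whose proliferation median was the highest (0.82 above the mean of the 4 libraries, against 0.28 in WT replicate 2), also stood apart in the list of p53 targets and cell cycle inhibitors, with -0.67 against 0.69 in WT replicate 2 and 0.24 and -0.08 in the Asxl1-/- libraries. In that list, with genes chosen after their values were seen, the p53 target Ccng1 stood at 17.8 FPKM in WT replicate 1 and 374 in WT replicate 2, against 258 and 106 in Asxl1-/-, and Mdm2 at 13.6 and 136 against 71.8 and 36.7. Members of that list did not all go this way. The cell cycle inhibitor Cdkn2a stood at 766 FPKM in WT replicate 1 and 82.3 in WT replicate 2, against 125 and 234 in Asxl1-/-. Cdkn2b, Cdkn2c and Cdkn1b were also highest in WT replicate 1, whereas Cdkn1a was lowest there. These genes, too, were chosen after their values were seen. Without WT replicate 1 the proliferation median was -0.86. Between the libraries low in macrophage markers (Asxl1-/- replicate 1 minus WT replicate 1) the median was -1.48, and between those high in them (replicates 2) it was -0.81.

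The hypoxia and glycolysis list was the other call. It rose by a median of 0.21 over 22 genes, 16 of them positive (camera adjusted p = 0.0269). The adjusted p was 0.975 with an estimated correlation, and no member passed, adjusted over the list alone or over all genes. Adm stood at 147 and 94.7 FPKM in Asxl1-/- against 12.8 and 27.5 in WT, the collagen hydroxylase P4ha2 at 83.5 and 85.8 against 38.5 and 46.0, and the glycolytic enzyme Pfkl at 76.3 and 58.6 against 34.2 and 44.1, while the hypoxia gene Ndrg1 stood lower, at 4.77 and 8.81 against 21.8 and 15.2. The call was lost without WT replicate 2, with a median of 0.068 (adjusted p = 0.315), and without Asxl1-/- replicate 1, with a median of 0.086 (adjusted p = 0.371); over the 4 fits that leave out a library the median ran from 0.068 to 0.478. After quantile normalization the median was larger, at 0.265, with an adjusted p of 0.0513. Of its 22 genes 9 were higher in both replicates 1 than in both replicates 2, where chance gives 16.7%. Its median was 0.22 between the libraries low in macrophage markers and 0.26 between those high in them.

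A further 4 lists lay at the threshold, and their calls come and go with the setting. The osteoblast list had a median of -0.63 with 13 of 14 members negative (camera adjusted p = 0.0553). Its master regulator Runx2 stood at 13.6 and 17.6 FPKM in WT against 5.73 and 7.32, and the collagen Col1a2 at 1564 and 2284 against 1178 and 1049. The osteoblast list median was 0.72 above the mean of the 4 libraries in WT replicate 2 and -0.18 in WT replicate 1. Cholesterol synthesis genes had a median of -0.46 with 17 of 22 negative (adjusted p = 0.0579), among them Pmvk at 24.8 and 13.3 FPKM in WT against 8.48 and 7.94. Matrix genes had a median of 0.41 with 19 of 31 positive (adjusted p = 0.0579); Col8a1 stood at 65.2 and 133 FPKM in Asxl1-/- against 18.6 and 21.9, and the hyaluronan synthase Has2 lower, at 0.886 and 3.59 against 10.0 and 13.4. Hox genes had a median of 0.23 with 14 of 24 positive (adjusted p = 0.0553). Hoxb9 stood at 9.08 and 2.02 FPKM in Asxl1-/- against 0.124 in WT replicate 2 and was listed at 0 in WT replicate 1. Both Asxl1-/- libraries lay above both WT libraries for 6 of the 24, against 15.6% of all genes tested. These were Hoxb3, Hoxb4, Hoxb6, Hoxb7, Hoxb8 and Hoxb9, neighbours on chromosome 11. All were listed at 0 in WT replicate 1 and reached at most 0.993 FPKM in WT replicate 2. No tested gene of the other Hox clusters did so. With an estimated correlation the adjusted p of each of the 4 was 0.975. In camera without the variance trend the osteoblast list was called lower (adjusted p = 0.0449) and the Hox list higher (adjusted p = 0.0439). The osteoblast list was also called lower by camera with no filter (adjusted p = 0.0308) and after median ratio scaling (0.0404). So it was with the macrophage covariate (0.0314) and with camera on ranks (0.0472). It was not called after quantile normalization or at a mean of at least 5 FPKM. Without WT replicate 1 the medians of the cholesterol synthesis, matrix and Hox lists had the other sign, at 0.096, -0.035 and -0.093. The osteoblast list was called lower in that setting, at -1.12 (adjusted p = 1.66e-05), and without Asxl1-/- replicate 2, at -1.03 (adjusted p = 0.00178), and stood at -0.33 without WT replicate 2 (adjusted p = 0.711).

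Lists that bear on stem cell identity and fate did not pass the camera test with all 4 libraries. Stromal support factors were called lower without Asxl1-/- replicate 2 (median -0.38, adjusted p = 0.0376), and contractile genes higher without WT replicate 2 (median 0.77, adjusted p = 0.00131) but not without WT replicate 1, where their median was -0.12. With all 4 libraries and an estimated correlation the adjusted p of both was 0.975. Markers of mesenchymal progenitors had a median of -0.34 over 21 genes (adjusted p = 0.841), with Nt5e (CD73) at 2.31 and 7.19 FPKM in WT against 0.493 and 0.507 and Alcam at 6.96 and 19.8 against 0.674 and 2.92. Factors by which stroma supports blood cells had a median of -0.39 over 18 genes (adjusted p = 0.781); the chemokine Cxcl12 stood at 641 and 744 FPKM in WT against 1297 and 947, and Angpt1 at 23.3 and 8.37 against 6.09 and 1.74. Adipocyte genes had a median of -0.02 over 20 genes (adjusted p = 0.795), with the fatty acid binding protein Fabp5 at 303 and 152 FPKM in WT against 76.6 and 112 and the lipase Pnpla2 at 3.46 and 3.53 against 5.34 and 6.71. Chondrocyte genes had a median of -0.49 over 5 (adjusted p = 0.950) and contractile genes of 0.46 over 13 (adjusted p = 0.245), with calponin Cnn1 at 42.0 and 93.2 in WT against 20.3 and 5.63. Self-renewal factors had a median of 0.12 over 10 genes (adjusted p = 0.788); Myc stood at 46.8 and 27.0 in WT against 20.0 and 7.90.

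Regulatory and stress lists did not pass with all 4 libraries either. Polycomb and BAP1 complex components had a median of -0.07 over 36 genes (adjusted p = 0.950), with the methyltransferase Ezh2 at 24.0 and 13.1 FPKM in WT against 7.06 and 6.30, and Pcgf5 at 6.42 and 5.35 against 11.6 and 12.7. The Wnt list had a median of 0.09 over 29 genes (adjusted p = 0.245); adjusted over the list alone Wif1 rose (0.0188 FPKM and listed at 0 in WT, 3.37 and 3.26 in Asxl1-/-) and Sfrp2 fell, and over all genes tested neither passed. The TGF-beta and BMP list had a median of 0.02 over 32 genes (adjusted p = 0.245; 0.44 and 0.0435 without WT replicate 1, 0.36 and 0.04 without Asxl1-/- replicate 1), the p53 target and cell cycle inhibitor list of 0.12 over 28 (adjusted p = 0.918; -0.75 and 0.000346 without WT replicate 1, 0.74 and 0.00131 without WT replicate 2) and apoptosis regulators of 0.16 over 21 (adjusted p = 0.561). The unfolded protein response had a median of 0.06 over 23 genes (adjusted p = 0.245), oxidative phosphorylation of -0.03 over 34 (adjusted p = 0.862) and inflammatory cytokines of -0.46 over 18 (adjusted p = 0.874), with the chemokine Ccl5 at 48.2 and 5.20 in WT against 2.10 and 0.401. The chemokine Ccl8 went the other way, listed at 0 and at 0.418 FPKM in WT against 5.44 and 2.29 in Asxl1-/-. The adjusted p of each of these lists was 0.975 with an estimated correlation. Median and test differed in sign for the adipocyte, chondrocyte, inflammatory, oxidative phosphorylation, interferon and macrophage lists, and median and mean for the adipocyte, apoptosis and self-renewal lists.

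Some gene groups differed between libraries of the same genotype; Lyz2 and Isg15 below were chosen as examples after their values were seen. Macrophage markers were higher in both replicates 2 than in both replicates 1 for 17 of 19 genes, where chance gives 16.7%. The lysozyme gene Lyz2 stood at 2.85 FPKM in WT replicate 1, 400 in WT replicate 2, 2.36 in Asxl1-/- replicate 1 and 293 in Asxl1-/- replicate 2. Interferon response genes went the other way for 26 of 32: Isg15 stood at 64.3 and 137 FPKM in WT replicate 1 and Asxl1-/- replicate 1, and at 4.35 and 0.531 in the replicates 2. Between genotypes the macrophage list had a median of -0.38 (camera adjusted p = 0.841) and the interferon list of -0.03 (adjusted p = 0.530). Both directions turned with single libraries left out, from -2.11 to 1.42 and from -1.29 to 1.36. Whole chromosomes also stood apart in single libraries, with the 405 genes of chromosome 3 at a median log2 difference of -0.595 in Asxl1-/- replicate 1 and 0.50 in WT replicate 1 against the other 3 libraries; the genes of chromosome 3 had a median fold change of -0.48 between genotypes and those of chromosome 10 of 0.27.

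**Figure D2:**
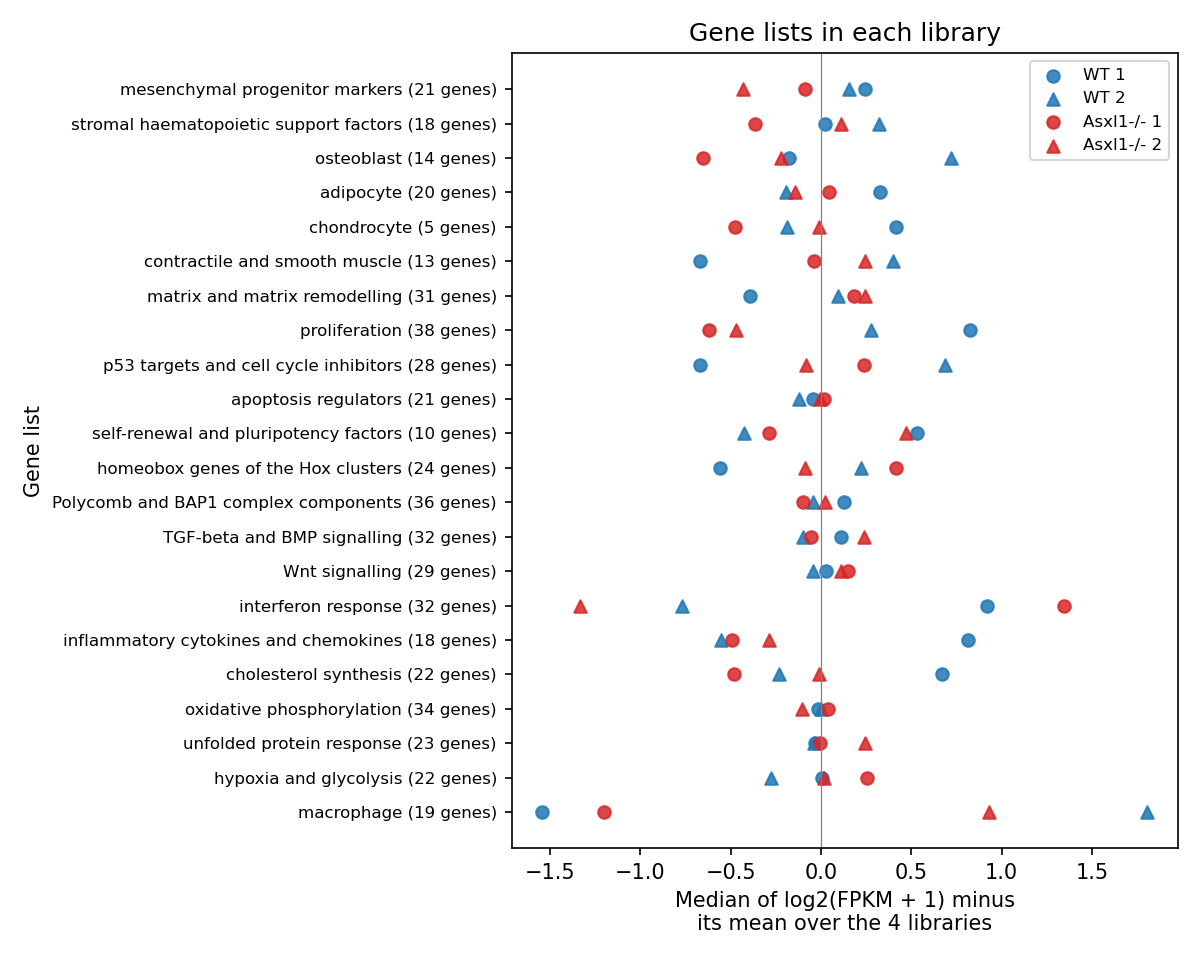
Each row is a gene list, with the number of tested genes in brackets, and each point (x axis) is the median over its genes of log2(FPKM + 1) in a library minus the mean over the 4 libraries; blue is WT and red Asxl1-/-, circles are replicate 1 and triangles replicate 2. The proliferation medians are 0.82 and 0.28 in WT and -0.62 and -0.47 in Asxl1-/-, whereas the macrophage and interferon medians part the replicates 1 from the replicates 2.

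**Figure D3:**
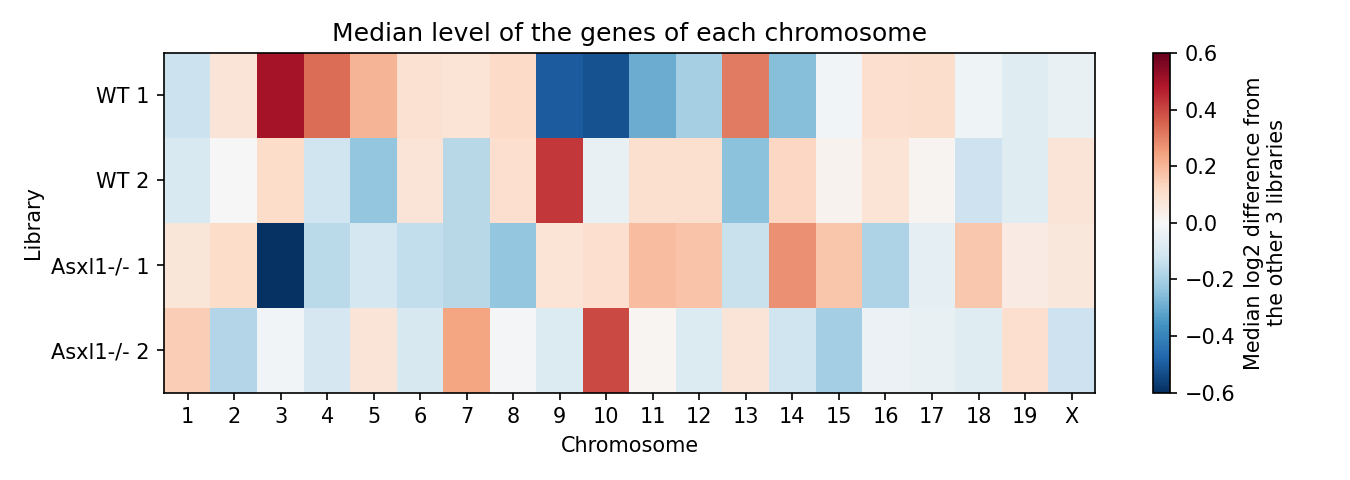
Median log2 difference of the genes of each chromosome (x axis; mean of at least 5 FPKM) in each library (rows) from the mean of the other 3 libraries, centred on the autosomes, with red for higher and blue for lower. The strongest colours are chromosome 3 in Asxl1-/- replicate 1 (-0.595), chromosomes 10 (-0.52), 9 (-0.50) and 3 (0.50) in WT replicate 1.

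Apart from macrophage markers, of which 19 of 22 reached the filter, markers of other cells and of sex were few. Of the osteoclast list 4 of 10 genes reached the filter, with Mmp9 at 3.72 and 0.99 FPKM in WT against 0.0498 and 0.0805. Of the granulocyte and mast cell list 1 of 16 did, the receptor Kit, at 12.2 FPKM in Asxl1-/- replicate 1 and at most 0.008 in the other libraries. The lymphoid list had 0 of 14. Of the erythroid and megakaryocyte list 2 of 15 passed the filter; adjusted over the list alone Ppbp fell, at 5.13 and 6.90 FPKM in WT against 0.0433 and 0.0467, and over all genes tested it did not pass. The endothelial list had 3 of 16, with Egfl7 at 6.21 and 2.71 in WT against 1.95 and 1.16, and the epithelial and neural list 2 of 15, with Krt19 at 74.7 FPKM in Asxl1-/- replicate 1 and at most 3.63 elsewhere. Of the sex-linked list, Xist, the RNA of the inactive X, stood at 0.0277 FPKM in WT replicate 1 and at 106, 106 and 94.9 in WT replicate 2 and the Asxl1-/- replicates, and 4 Y-linked genes were listed at 0 in all 4 libraries.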

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

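The limma fits without genes under 300 bp, with macrophage markers as covariate and with chromosome medians removed were chosen after the data were seen. So was camera's variance-trend option, with which 1 list was called higher and 1 lower, against 2 and 2 without it. The use of medians to judge turned directions was also chosen afterwards. The other settings were set before. Causes were not tested except where the setting itself shows them. No paired analysis was possible because replicate numbers follow accession order only. Asxl1 kept its direction in all 15 alternatives. Its groups did not overlap, so no fit that leaves out a library could turn its sign. With all 4 libraries its limma adjusted p under the alternatives ran from 0.164 to 0.522. The proliferation list kept its call (adjusted p 4.07e-21 to 1.48e-12) in all 16 alternatives other than the estimated correlation and fry, which call 0 lists higher and 0 lower (adjusted p = 0.975 and 0.992); fry asks whether a list moves at all and compares it with no other genes. With each library left out, where the lone library is assumed to vary like the other group, the proliferation median ran from -1.36 to -0.86. Over these fits genes called lower numbered 1 to 6 (main 3), genes called higher 0 to 4 (main 0), genes with an unadjusted p under 0.05 588 to 1352 (main 909), lists higher 3 to 5 (main 1) and lists lower 2 to 4 (main 1). Genes lower numbered 1 with no filter and 0 without genes under 300 bp, which takes out all 3 calls. Lists higher and lower numbered 2 and 2 with no filter, 2 and 2 at a mean of at least 5 FPKM, 2 and 2 in eBayes without trend, and 3 and 3 with the macrophage covariate. They numbered 1 and 2 after median ratio scaling, 0 and 2 after quantile normalization, 2 and 1 with chromosome medians removed, and 1 and 3 with camera on ranks. The lists that entered or left in these settings were hypoxia, osteoblast, Hox, matrix and cholesterol synthesis. The authors' calls, 70 higher and 51 lower, were the same with an absolute log2 fold change of at least 1.

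Medians of lists not called turned sign as follows. Self-renewal factors stood at -0.015 with a pseudocount of 0.1. With no filter the chondrocyte list stood at 0.001, TGF-beta and BMP at -0.017 and Wnt at -0.034; at a mean of at least 5 FPKM mesenchymal progenitor markers stood at 0.352, Hox genes at -0.494 and TGF-beta and BMP at -0.01. After median ratio scaling and quantile normalization adipocyte genes stood at 0.085 and 0.05, Polycomb components at 0.021 and 0.065 and interferon genes at 0.056 and 0.026; oxidative phosphorylation stood at 0.082 after the former. With chromosome medians removed adipocyte genes stood at 0.017, TGF-beta and BMP at -0.006, interferon genes at 0.022, and the genes Ndufb5 at 0.029 and Ctsk at 0.246. With each library left out the medians ran from -0.215 to 0.201 for adipocyte, -0.123 to 0.771 for contractile, -0.035 to 0.555 for matrix, -0.747 to 0.735 for p53 target, -0.093 to 0.709 for Hox, -0.141 to 0.019 for Polycomb, -1.287 to 1.361 for interferon, -1.185 to 0.47 for inflammatory, -0.894 to 0.096 for cholesterol synthesis, -0.136 to 0.052 for oxidative phosphorylation, -0.551 to 0.458 for self-renewal, -0.051 to 0.438 for TGF-beta and BMP, -0.025 to 0.201 for Wnt, -2.106 to 1.416 for macrophage, -0.637 to 0.043 for mesenchymal progenitor and -0.086 to 0.271 for unfolded protein response genes. With a library left out the contractile, matrix, Hox and TGF-beta and BMP lists were each called higher in some of these fits, the osteoblast (-1.117 to -0.333), cholesterol synthesis and stromal support lists (-0.596 to -0.124) lower, and hypoxia, at 0.068 to 0.478, lost its call in 2. Without a turn of sign, the chondrocyte median ran from -0.726 to -0.025 and that of apoptosis regulators from 0.05 to 0.172. The p53 target, interferon and macrophage lists were called in opposite directions depending on the library left out. Log2 fold changes of named genes ran from -0.073 to 6.623 for Xist, -2.395 to 0.5 for Csf1r, -2.052 to 0.555 for Itgam, -0.133 to 2.508 for Oas2, -0.173 to 1.264 for Ifit2, -0.076 to 1.014 for Tubb3, -0.978 to 4.799 for Krt19, -0.434 to 0.099 for Ctsk and -0.007 to 3.012 for Cdh5. Of the 20 genes named by the rule for the largest differences, 7 moved by over 1.5 times with a library left out. That 0 turned sign was fixed in advance, since the rule takes only genes with no overlap between the groups. The other 1728 values of named genes under an alternative kept direction and side of the threshold. No named gene had passed the threshold in the main fit. For those whose groups do not overlap, leaving out a library could not turn the sign.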

Other observations

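Some developmental genes were near 0 in some cultures and well expressed in others of the same genotype; they were picked after their values were seen. The hindlimb regulator Pitx1 was listed at 0 in WT replicate 1 and Asxl1-/- replicate 2 and stood at 6.71 and 8.12 FPKM in WT replicate 2 and Asxl1-/- replicate 1, and Hoxa11 followed the same libraries, at 8.75 and 16.7 FPKM. The homeobox gene Meox2 did the reverse, at 16.1 FPKM in WT replicate 1 and 59.7 in Asxl1-/- replicate 2. Mest, an imprinted gene, parted by genotype instead, at 19.1 and 17.2 FPKM in WT against 0.255 and 1.30 in Asxl1-/-. The X-linked gene Xlr3a stood at 31.2 FPKM in Asxl1-/- replicate 1 and was listed at 0 elsewhere. Of the 3 ways to part the 4 libraries into pairs, too few for a share under 0.05, the genotypes gave 3 genes at an adjusted p under 0.05 in limma and 909 at an unadjusted p, WT replicate 1 with Asxl1-/- replicate 2 against the others gave 7 and 598, and replicates 1 against replicates 2 gave 2 and 337.

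Of the tests in the next paragraphs, those on the share of macrophage RNA, on scaling, on gene length and GC content, on Y-linked genes and on the activity of X-linked genes were chosen after the result was seen. The chromosome medians had also been seen before the tests on chromosomes and on loss of an X were planned. The tests on length and GC content replaced a linear fit on both, which for the fold changes moved genes by 0.042 at the 95th percentile and so decides little, and the test on macrophage RNA replaced a comparison of 1 library with 1. The test on Y-linked genes was changed once: as first written it took all 109 rows on the Y chromosome, and its outcome then spoke for male cells, because Erdr1, which lies in the region shared with the X, stood at 32.7 FPKM in WT replicate 1 and at 17.6, 22.2 and 40.2 in WT replicate 2 and Asxl1-/- replicates 1 and 2. It was then narrowed to the 4 Y-linked genes of the sex-linked list, which turned the outcome.

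The proliferation list was lower in both Asxl1-/- libraries. Of 19 macrophage markers, 17 were higher in both replicates 2 than in both replicates 1, and 1 parted by genotype. Those 17 could not also part by genotype, so the count of 1 was bounded beforehand and is no separate test. That the levels followed the replicates argues against a different share of macrophage RNA as the whole cause. The proliferation medians were -1.48 between the libraries low in these markers and -0.81 between those high in them, each 1 library against 1. The scaling between libraries is argued against as well, since the median nearer to 0 of median ratio scaling and quantile normalization was -1.001, and so are gene length and GC content, since the 20 genes nearest to each member in both had a median log2 fold change of -0.052. WT replicate 1, with the highest proliferation median, had low levels of p53 targets such as Ccng1 and Mdm2. Whether these are linked was not tested, and without that library the list median was -0.86. Passage number (5 to 10 by the labels) and cell density at harvest may also set the level of these genes and were not tested, so an effect of Asxl1 loss on cell division remains a hypothesis beside them.

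Whole chromosomes were shifted in single libraries. Of 76 pairs of library and autosome, 38 had a median beyond the limit of 0.108 that shuffled genes gave, which argues against scatter of single genes. Each library was set against the mean of the others, so a shift in 1 library also moves the others the opposite way. The pairs are therefore not separate events, and neither are the values of chromosome 3 in Asxl1-/- replicate 1 and WT replicate 1. In the 4 largest (chromosome 3 in Asxl1-/- replicate 1, and 10, 9 and 3 in WT replicate 1) 100% of the 10 Mb bins had the sign of the chromosome, which argues against a few clusters of neighbouring genes, and genes of other autosomes matched on length and GC content had medians of the opposite sign in each of the 4 (-2.6% to -6.7% of the shift), which argues against those properties. Genes above and below the median level shifted alike, with a ratio of the smaller to the larger shift of at least 0.846, which is consistent with gain or loss of chromosome copies in part or all of a culture; no DNA was analysed here. As a hypothesis, chromosome copies that differ between cultures may add to fold changes between genotypes, such as the median of -0.48 on chromosome 3; with chromosome medians removed the proliferation list still stood at -1.16.

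Xist was near 0 in WT replicate 1 and near 100 FPKM in the other 3 libraries. A culture of male cells that kept their Y is argued against, since the highest Y-linked gene of the sex-linked list stood at 0 FPKM; Erdr1 was the only one of the 109 rows above 0. Male cells that had lost their Y were not tested and stay open. A second active X is argued against by the median of X-linked genes, -0.046 relative to the other 3 libraries. Loss of 1 X chromosome stays open: the 8 genes that escape X inactivation had a median of -0.24, close to the bound of -0.25 set beforehand, and 4 of them were lowest in WT replicate 1. No biological explanation by genotype was tested for this library.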
